A study of Homo sapiens with 12 samples.

How the data were processed

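RNA was measured on 12 Affymetrix HG-U133 Plus 2.0 arrays, 1 per sample, each holding 54675 probe sets. The samples came from NCI-H1299, an established human non-small cell lung cancer line, in 4 groups of 3: parental cells grown in medium with serum, spheroid cells grown in a stem cell medium, and xenograft tumours grown from each of these. Per the labels' protocols, monolayer cells were kept in the stem cell medium for 7 to 10 days, and the floating cells were then placed in flasks that hinder attachment. Total RNA was purified on columns and 2 µg of it was labelled with biotin by a one-cycle kit, per the same protocols. The titles call the 3 samples of a group biological replicates. Whether each tumour came from its own animal is not given in the sources used here, so the p-values measure the spread between these samples, part of which may be technical.

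The deposited values are log2 expression values, 1 per probe set and array, and the tools named with them are RMA and the R package affy, per the submitters' processing notes. Tool versions, and whether all 12 arrays were normalised together, are not given in the sources used here. The log2 scale was read from the range of the deposited values. No coordinates are printed, because no genome build is given for the array annotation in the sources used here.

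In the platform annotation 41091 probe sets had 1 gene symbol, 1801 had several and 11783 had none. The table held 62 control probe sets. The annotation can be old, so symbols were looked up by gene number for 41037 probe sets in a gene table of the GRCh38.p14 assembly. Genes were named only from probe sets with 1 symbol. Each of the 19775 genes was represented by its probe set with the highest mean over the 12 arrays, with no filter on dim probe sets.

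All computing used R 4.3.3 and limma 3.58.1. A linear model with 1 mean per group was fitted to the 12 arrays (8 residual degrees of freedom) and moderated by limma's eBayes, so that all groups shared 1 estimate of the spread per gene. The 5 comparisons were spheroid minus parental in culture, the same in xenografts, xenograft minus culture for parental cells, the same for spheroid cells, and the spheroid to parental difference in xenografts minus that in culture (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, and all tests were two-sided. Differences are in log2 units with the standard error (SE) of the fit, and levels are group means ± SD over 3 arrays. The number of arrays limits the precision: the median SE was 0.20 for a difference of groups and 0.28 for the interaction. An exact permutation test of 1 gene with 3 against 3 arrays cannot go below p = 0.1, so single genes rest on the model.

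There were 44 gene lists, 36 of pathways or cell states and 8 of markers of other cell types that a tumour in an animal could hold. Of their 787 genes, 717 were represented. Lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 44 lists. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. In the order of the comparisons above, 0, 2, 2, 0 and 3 lists passed with the estimated correlation. Fry called 0, 3, 9, 0 and 4 lists. At the preset correlation regrouped arrays called as many lists as the real groups in culture, between xenografts and in spheroid cells.

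Named genes followed a rule. For each comparison it takes the 8 highest and the 8 lowest log2 differences among called genes, outside the interaction only where the 3 values of each group did not overlap. It leaves out control probe sets, probe sets with several or no symbols, and symbols that start with LOC, FAM or KIAA, contain orf, or end in -AS1 or -IT1. For each of up to 10 lists with the lowest camera adjusted p under 0.05 it adds the 3 called members with the largest absolute difference, or the member with the lowest p where none was called. It always adds every called member of the stem cell marker list and PROM1, CD44, ALDH1A1, SOX2, POU5F1 and NANOG. From each cell type marker list it adds the 2 members with the highest xenograft minus culture difference. The text may name fewer, in that order. POU5F1 was read only by probe sets with several symbols and has no value here.

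The groups, comparisons, their tests, the lists, this rule and the alternatives were chosen before the data were examined. The tests of explanations for array spread, for the hypoxia list, for the HBE1 probe set and for the genes lower in spheroid xenografts were chosen after the results were seen. The exceptions among the alternatives are array spread as a covariate, leaving out the widest or the narrowest array of each group, and the replicate block fitted to only the groups compared. The other alternatives were quantile normalisation again, within all arrays or within culture and xenografts separately, median centring, cyclic loess, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, only genes above the median level, trend and robust eBayes, array weights, the replicate number as a block, only the groups compared, other thresholds, all probe sets, Spearman's rho, and leaving out each array in turn.

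Correlations over genes between differences that share no array were tested by exact permutation of the array labels (400 relabellings, smallest possible p 0.01). Differences that share the parental culture arrays were set beside 1000 simulated data sets of unchanged groups. Of all pairs of arrays 0 held identical values, and correlations between arrays ran from 0.952 to 0.994.

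The replicate numbers in the titles were checked as a pairing through the correlation, over genes, of deviations from the group means. Every correlation between arrays of the same number was above 0.1 between spheroid culture and spheroid xenografts (0.341, 0.333 and 0.431) and between parental and spheroid xenografts (0.182, 0.213 and 0.482). Replicate 3 was the widest array of each of these groups, so array spread rather than pairing may give these values. For the comparisons of these groups the fit with the replicate number as a block is given beside each result whose call it changes.

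The fit was tested on simulated data for each comparison with 200 of 19775 genes changed. For spheroid minus parental in culture it recovered 58.5% of genes changed by 1 log2 unit and 97.5% of those changed by 2, and for the interaction 2% and 89.5%.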

Results

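Gene expression was measured in NCI-H1299 cells and in tumours grown from them, with 3 samples each of parental culture, spheroid culture, parental xenografts and spheroid xenografts. Spheroids are floating clusters that form in stem cell medium, and the series design calls these cells cancer stem cells. The comparisons ask how spheroid cells differ from parental cells, in culture and in tumours, and how each kind of cell changes when it grows as a tumour.

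The array medians ran from 5.85 to 6.03 in log2 units, and the interquartile ranges from 2.82 on parental culture replicate 1 to 3.44 on parental culture replicate 2. Parental culture was the most variable group, with a median SD per gene of 0.316, against 0.186 in spheroid culture, 0.199 in parental xenografts and 0.156 in spheroid xenografts. The probe set for the 5' part of 18S ribosomal RNA read 6.96 on parental culture replicate 1 and 10.50 on replicate 2, against 12.21 to 13.34 on the other arrays. The difference of GAPDH 3' and 5' signals was 0.49 on parental culture replicate 1, against 0.019 to 0.13 on the other 11 arrays. That of actin was 0.78 there, 0.77 on spheroid culture replicate 1 and 0.64 on spheroid xenograft replicate 3, against 0.18 to 0.38 on the other 9. The array closest to parental culture replicate 2 was parental xenograft replicate 3 (r = 0.976 over probe sets). The first component of the variation within groups held 48.5% of it, and the scores of the 12 arrays on it correlated with their interquartile ranges (r = 0.989).

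**Figure D1:**
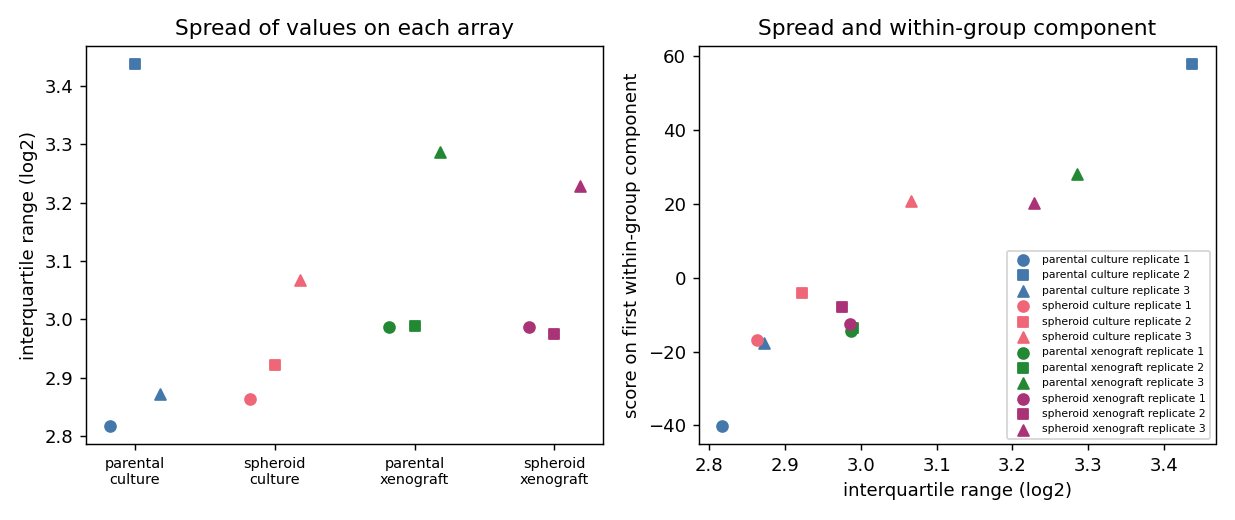
The left panel plots the interquartile range of the log2 values on each of the 12 arrays by group, and the right panel plots the score of each array on the first component of the within-group variation against that range. Parental culture holds the narrowest array (2.82, score -40.2) and the widest (3.44, score 57.9).

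Between parental and spheroid culture, the lists of the hypoxia response and of glycolysis were higher in spheroids by camera at the preset correlation, and those of S phase, of G2 and M phase and of the ATF4 amino acid stress response were lower. None of these 5 lists passed with an estimated correlation (adjusted p from 0.814 to 0.888). Of 23 measured hypoxia genes 5 rose and 0 fell (8 rose adjusted over the list alone; median 0.84; camera adjusted p = 1.73e-06, but adjusted p = 0.814 with an estimated correlation). They included ADM, which encodes the vasodilator adrenomedullin (2.41, SE 0.41), ANKRD37 (2.13, SE 0.45) and P4HA1, a collagen prolyl hydroxylase (1.57, SE 0.32). Of 16 glycolysis genes 1 rose (1 adjusted over the list alone), the aldolase ALDOC (1.71, SE 0.28), and the list had a median of 0.35 (adjusted p = 0.00219, and adjusted p = 0.814 with an estimated correlation).

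Of 21 ATF4 targets 2 fell in spheroid culture (6 adjusted over the list alone): CHAC1, a glutathione-degrading enzyme (-1.53, SE 0.25), and the glycoprotein hormone STC2 (-0.87, SE 0.17). The list had a median of -0.33 (adjusted p = 6.76e-05, and adjusted p = 0.814 with an estimated correlation). Of 23 S phase genes 1 fell (5 adjusted over the list alone), the flap endonuclease FEN1 (-0.84, SE 0.17), with a median of -0.31. Camera gave the list adjusted p = 1.73e-06, and adjusted p = 0.814 with an estimated correlation. Of 25 G2 and M phase genes 0 fell (0 adjusted over the list alone). Their median was -0.23 (adjusted p = 0.00168, and adjusted p = 0.888 with an estimated correlation), and the spindle motor KIF11 differed by -0.59 (SE 0.22, adjusted p = 0.217).

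MFAP5, a microfibril protein of the extracellular matrix, rose from 5.44 ± 0.36 in parental to 11.17 ± 1.05 in spheroid culture (SD, n = 3 arrays per group), a difference of 5.73 (SE 0.86, limma adjusted p = 0.00712). The membrane adaptor ANK3 rose from 5.78 ± 0.60 to 9.78 ± 0.84, and the tetraspanin TSPAN13 rose by 3.77 (SE 0.51) and PLD5 by 3.60 (SE 0.50). CTCFL, a germline paralogue of the insulator protein CTCF, rose by 2.77, the ephrin ligand EFNB2 by 2.64, the dipeptidase DPEP3 by 2.63 and the protease inhibitor TFPI2 by 2.42. NIBAN1 (-3.21, SE 0.52) and CNKSR2, a scaffold of Ras signalling (-3.17, SE 0.37), fell. So did the tubulin TUBB2B (-3.10), the pentraxin PTX3 (-3.06), PHLDB2 (-3.05), the secreted protein DKK3 (-3.04), the fucosyltransferase FUT9 (-2.99) and SH3BGRL (-2.95). For PHLDB2 3 of 5 probe sets had that sign, and for FUT9 2 of 3. When probe sets ending in _x_at or _s_at were left out, so that others stood for these genes, the difference was 0.31 for ANK3 (adjusted p = 0.681), 2.22 for TFPI2 (adjusted p = 0.0952), -0.58 for PHLDB2 (adjusted p = 0.432), 0.050 for P4HA1 (adjusted p = 0.920) and -0.60 for STC2 (adjusted p = 0.479), and none was called. With the mean of all probe sets of a gene TFPI2 (0.0618) and STC2 (0.109) were not called either, and over all alternatives the adjusted p of these genes ran from 1.49e-04 to 0.920.

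By limma 487 of 19775 genes differed between spheroid and parental culture, 175 higher and 312 lower in spheroids, with 108 and 229 of these at 2-fold or more. After median centring 350 (77 higher and 273 lower) passed, after quantile normalisation again 1096, after cyclic loess 971, and with only the 6 culture arrays in the fit 15. The count was 77 without spheroid culture replicate 2, 157 without spheroid culture replicate 3 and 264 without parental culture replicate 3. It was 316 without spheroid xenograft replicate 2, 763 without parental culture replicate 2 and 853 without parental culture replicate 1. Of the 25 genes named here as called, TSPAN13, PLD5, CTCFL, DPEP3, CNKSR2, TUBB2B and PHLDB2 stayed called whichever array was left out, and the other 18 were not called without spheroid culture replicate 2 (adjusted p up to 0.204 over the 12 fits). Of those 7, with only the culture arrays in the fit TSPAN13 (adjusted p = 0.0652), PLD5 (0.0697), CTCFL (0.0574), DPEP3 (0.0518) and TUBB2B (0.0781) were not called. Nor was PLD5 without the widest array of each group (0.0574), and the adjusted p of these 5 ran from 2.22e-05 to 0.0781 over their alternatives. By camera 5 of 44 lists passed (0 with an estimated correlation, 1 at an unadjusted p under 0.05), 8 without parental culture replicate 2, 12 without spheroid culture replicate 1 and 10 without spheroid culture replicate 2. ATF4 targets did not pass without parental culture replicate 2 (adjusted p = 0.177; range over their alternatives 1.66e-09 to 0.177). G2 and M phase did not pass without parental culture replicate 2 (0.0621), without replicate 3 (0.0977) or without the widest array of each group (0.186; range 7.45e-07 to 0.186). Glycolysis did not pass without parental culture replicate 1 (0.157), without probe sets ending in _x_at or _s_at (0.0560) or without the narrowest array of each group (0.233; range 4.73e-04 to 0.233).

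**Figure D2:**
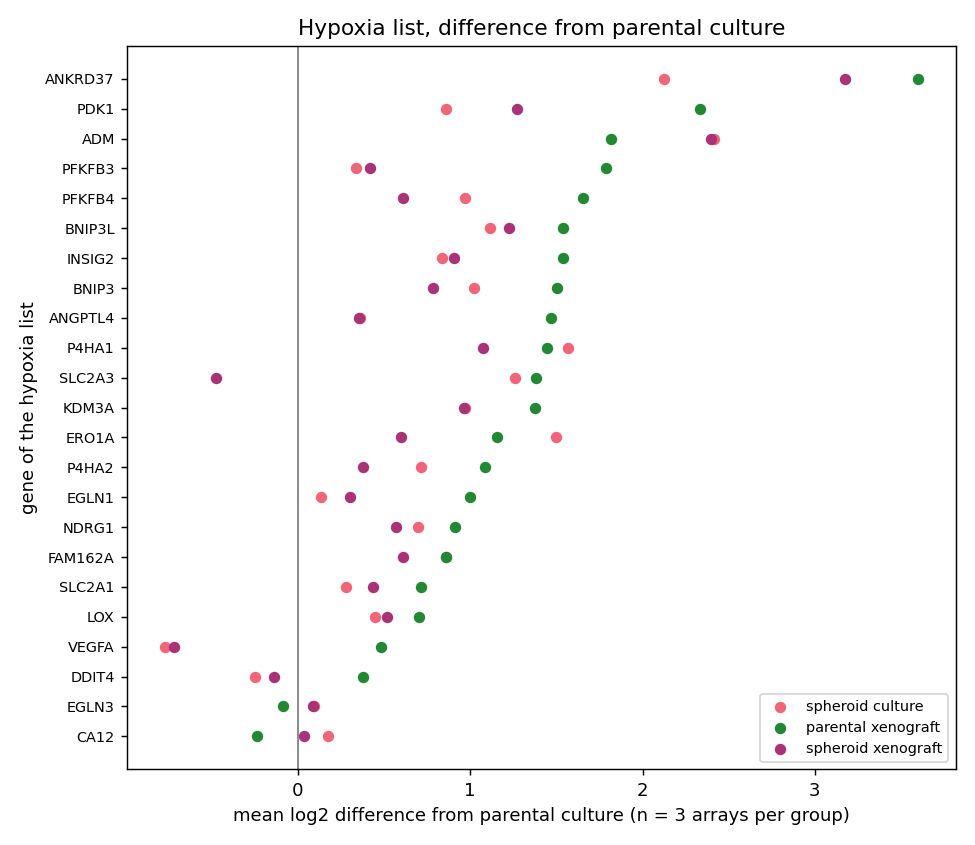
Each line holds 1 of the 23 measured genes of the hypoxia list, and points give its mean log2 difference from parental culture (3 arrays per group) in spheroid culture, parental xenografts and spheroid xenografts. The medians are 0.84, 1.37 and 0.57 in that order.

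Of the 22 stem cell markers represented 0 rose and 2 fell in spheroid culture (0 and 2 adjusted over the list alone). CD44, a hyaluronan receptor used to sort stem-like tumour cells, fell from 11.06 ± 0.48 to 9.27 ± 0.70 (SD, n = 3 arrays per group), a difference of -1.79 (SE 0.33, limma adjusted p = 0.0167), with the same sign on 11 of its 13 probe sets. ABCB1, a drug efflux pump, fell by 1.38 (SE 0.26). With the mean of all its probe sets CD44 differed by -0.85 (adjusted p = 0.129; range over its alternatives 4.86e-04 to 0.148). PROM1 differed by -0.022 (SE 0.16), ALDH1A1 by 0.15 (SE 0.14), SOX2 by -0.26 (SE 0.16) and NANOG by -0.19 (SE 0.19), and none of these 4 was called. On every array PROM1 and ALDH1A1 lay between 3.98 and 4.46, below the lower quartile of all values (4.63 to 4.80 over the arrays), and a change in genes this dim may not have been detectable. ABCB1 lay below that quartile too in spheroid culture and in both kinds of xenograft (4.02 to 4.61), so its difference is measured against a level this low and its size is uncertain. The list as a whole had a median of 0.034 and a mean of -0.13, opposite in sign, and did not pass camera in any comparison (adjusted p = 0.719 in culture, 0.442 between xenografts, 0.436 and 0.446 for xenograft minus culture in parental and spheroid cells, and 0.986 for the interaction). The call of CD44 was lost without parental culture replicate 3, spheroid culture replicate 2 or spheroid culture replicate 3 (adjusted p up to 0.0998), and that of ABCB1 without either of those spheroid arrays (up to 0.104).

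**Figure D3:**
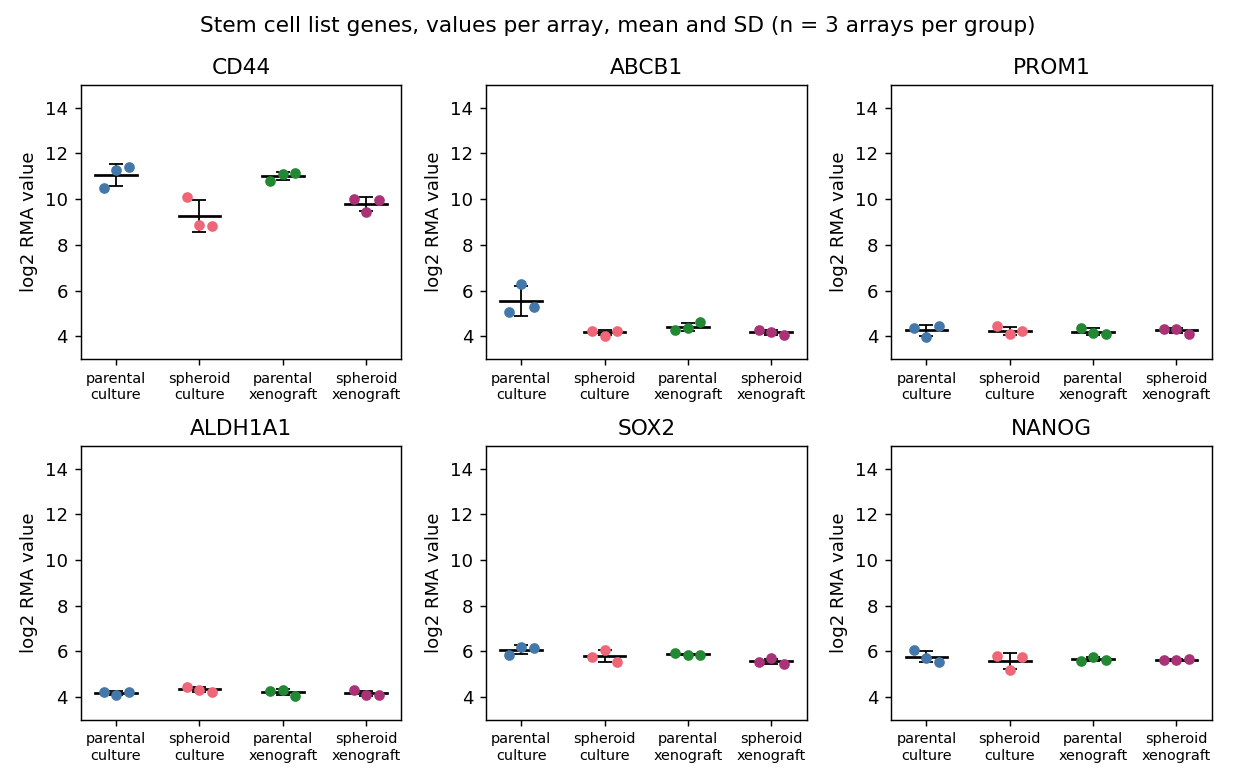
Each panel plots the log2 values of 1 gene on the 12 arrays by group, with the mean as a line and the SD as bars (n = 3 arrays per group). CD44 and ABCB1 are lower in spheroid than in parental culture, and PROM1, ALDH1A1, SOX2 and NANOG have no called difference.

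The lists of mesenchymal and matrix protease genes were lower in tumours from spheroid cells than in tumours from parental cells. SPARC, a secreted collagen-binding protein, stood at 8.96 ± 0.060 in parental and 4.71 ± 0.20 in spheroid xenografts (SD, n = 3 arrays per group), a difference of -4.25 (SE 0.14, limma adjusted p = 3.02e-08). Without probe sets ending in _x_at or _s_at another SPARC probe set gave -1.57 (adjusted p = 0.0578; range over its alternatives 2.00e-10 to 0.0578), which did not pass. SPARC and SNAI2, a transcription factor of the epithelial to mesenchymal transition (-1.06, SE 0.13), were the 2 of 16 mesenchymal genes that fell (5 adjusted over the list alone), and the list had a median of -0.50 (camera adjusted p = 1.57e-09, and adjusted p = 0.0146 with an estimated correlation). Of 18 matrix metalloproteinases and related genes 1 fell (5 adjusted over the list alone), the protease ADAMTS1 (-1.67, SE 0.28), with a median of -0.69. The test of this list gave adjusted p = 1.04e-06, and adjusted p = 0.0188 with an estimated correlation.

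Markers of fibroblasts, a cell type a tumour can draw from its host, moved with these lists: 1 of 17 fell (2 adjusted over the list alone), the protease FAP (-1.35, SE 0.22), with a median of -0.17. The list had adjusted p = 2.19e-05, and adjusted p = 0.293 with an estimated correlation. Endothelial markers (median 0.089, adjusted p = 0.338) and myeloid markers (-0.028, 0.785) did not pass, nor did those of lymphocytes (adjusted p = 0.740), skeletal muscle (0.163), adipocytes (0.397), erythroid cells (0.879) or keratinocytes (0.442). Of 18 integrins and laminins 2 fell (4 fell and 2 rose adjusted over the list alone), ITGB8 (-2.74, SE 0.48) and ITGA1 (-1.53, SE 0.22), with a median of -0.24. Camera gave the list adjusted p = 0.0109, and adjusted p = 0.122 with an estimated correlation.

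Of 24 interferon response genes 0 passed over all genes and 8 rose adjusted over the list alone, with a median of 0.37. The test of this list gave adjusted p = 1.57e-09, and adjusted p = 0.0776 with an estimated correlation, and IFI6 differed by 1.09 (SE 0.20, adjusted p = 0.0549). Of 23 hypoxia genes 0 passed and 2 fell adjusted over the list alone, with a median of -0.52. The list had adjusted p = 5.00e-08, and adjusted p = 0.218 with an estimated correlation, and the glucose transporter SLC2A3 differed by -1.86 (SE 0.36, adjusted p = 0.0652). Genes of cholesterol synthesis (median -0.40, 3 of 19 fell adjusted over the list alone) had adjusted p = 3.00e-05, and adjusted p = 0.447 with an estimated correlation. Neuroendocrine genes (median -0.10, 1 of 17 fell adjusted over the list alone) had adjusted p = 0.0109, and adjusted p = 0.315 with an estimated correlation. ATF4 targets were higher as a list (median 0.28, 0 of 21 adjusted over the list alone; adjusted p = 0.00608, and adjusted p = 0.763 with an estimated correlation). Over all genes no member of these 3 lists passed: STARD4, a sterol carrier, differed by -0.77 (adjusted p = 0.201), the granule protein SCG2 by -3.24 (0.111) and VLDLR, a lipoprotein receptor on the ATF4 list, by -1.19 (0.246), against the direction of that list.

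Among single genes MGP, an inhibitor of matrix calcification, was lower in spheroid than in parental xenografts (-4.97, SE 0.74). So were the potassium channel KCNJ2 (-4.11, SE 0.37), the chromatin organiser SATB1 (-3.91, SE 0.57), the actin-binding protein CAP2 (-3.54), the glycoprotein hormone STC1 (-3.43), the homeobox gene PRRX1 (-3.14, SE 0.28) and the glutathione transferase MGST1 (-3.04). PLD5 (3.17, SE 0.50), DMKN (1.93, SE 0.33), ALDOC (1.68, SE 0.28) and the troponin TNNI3 (1.54, SE 0.25) were higher. CCDC62 (1.34), SYTL3 (1.09, the same sign on 3 of 4 probe sets), PARP14 (0.94) and STAG3L3 (0.92) were higher too. With the replicate number as a block 5 of these genes were no longer called: PLD5 (adjusted p = 0.0530; range over its alternatives 3.94e-04 to 0.187), SYTL3 (0.0530; 5.63e-04 to 0.255), STAG3L3 (0.0549; 8.63e-04 to 0.397), ALDOC (0.0573; 7.99e-04 to 0.241) and ITGB8 (0.0751; 5.63e-04 to 0.248). CD44 differed by -1.22 (SE 0.33, adjusted p = 0.212) between the xenografts. Without probe sets ending in _x_at or _s_at other probe sets gave -0.67 for MGP (adjusted p = 0.993), -0.89 for SATB1 (adjusted p = 0.614) and -0.21 for MGST1 (adjusted p = 1.00), and DMKN (0.0553), ALDOC (0.0514), SYTL3 (0.0552) and ITGB8 (0.0578) were not called at an unaltered difference. With the mean of all probe sets SYTL3 (0.241), PARP14 (0.102), MGP (0.0686), ADAMTS1 (0.128) and ITGB8 (0.163) were not called, and over all alternatives the adjusted p of these genes ran from 1.77e-04 to 1.00.

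By limma 46 genes differed between spheroid and parental xenografts, 10 higher and 36 lower, 7 and 35 of them at 2-fold or more. After median centring 20 (2 higher and 18 lower) passed, after quantile normalisation within culture and within xenografts 69 (22 higher and 47 lower), after cyclic loess 28, and with only the 6 xenograft arrays 161. With the replicate block and only the xenograft arrays, a fit chosen after seeing the data, 491 (215 higher and 276 lower) passed. In it SLC2A3 (adjusted p = 0.0228), STARD4 (0.0441), VLDLR (0.0165), SCG2 (0.0165) and CD44 (0.0292) were called lower, and the list of fatty acid synthesis passed too (adjusted p = 0.0388, lower in spheroid xenografts, but adjusted p = 0.681 with an estimated correlation). SPARC, KCNJ2 and PRRX1 were the 3 of 21 genes named as called that stayed called whichever array was left out, and the other 18 were not called without spheroid xenograft replicate 2 (adjusted p up to 0.255 over the 12 fits). Of those 3, KCNJ2 (adjusted p = 0.0501) and PRRX1 (0.0503) were not called without the narrowest array of each group (range 1.20e-06 to 0.0503). The count was 4 without spheroid xenograft replicate 2, 10 without parental xenograft replicate 2, 11 without spheroid xenograft replicate 1, 20 without spheroid xenograft replicate 3 and 23 without parental culture replicate 3. It was 27 without spheroid culture replicate 3, 29 without spheroid culture replicate 2, 29 without parental xenograft replicate 1, 106 without spheroid culture replicate 1 and 140 without parental culture replicate 2. By camera 9 lists passed (2 with an estimated correlation), and 15 without spheroid xenograft replicate 3. ATF4 targets did not pass without parental xenograft replicate 1 (adjusted p = 0.0562; range 5.50e-05 to 0.0562), and neuroendocrine genes did not pass without replicate 2 (0.0882; range 0.00283 to 0.0882). Integrins and laminins did not pass without parental xenograft replicate 1 (0.0509), after cyclic loess (0.0644) or with array spread as a covariate (0.0540; range 0.00355 to 0.508). Among genes above the median level the lists of neuroendocrine genes (0.0720), integrins and laminins (0.508) and fibroblast markers (0.305; range 3.64e-08 to 0.305) did not pass.

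**Figure D4:**
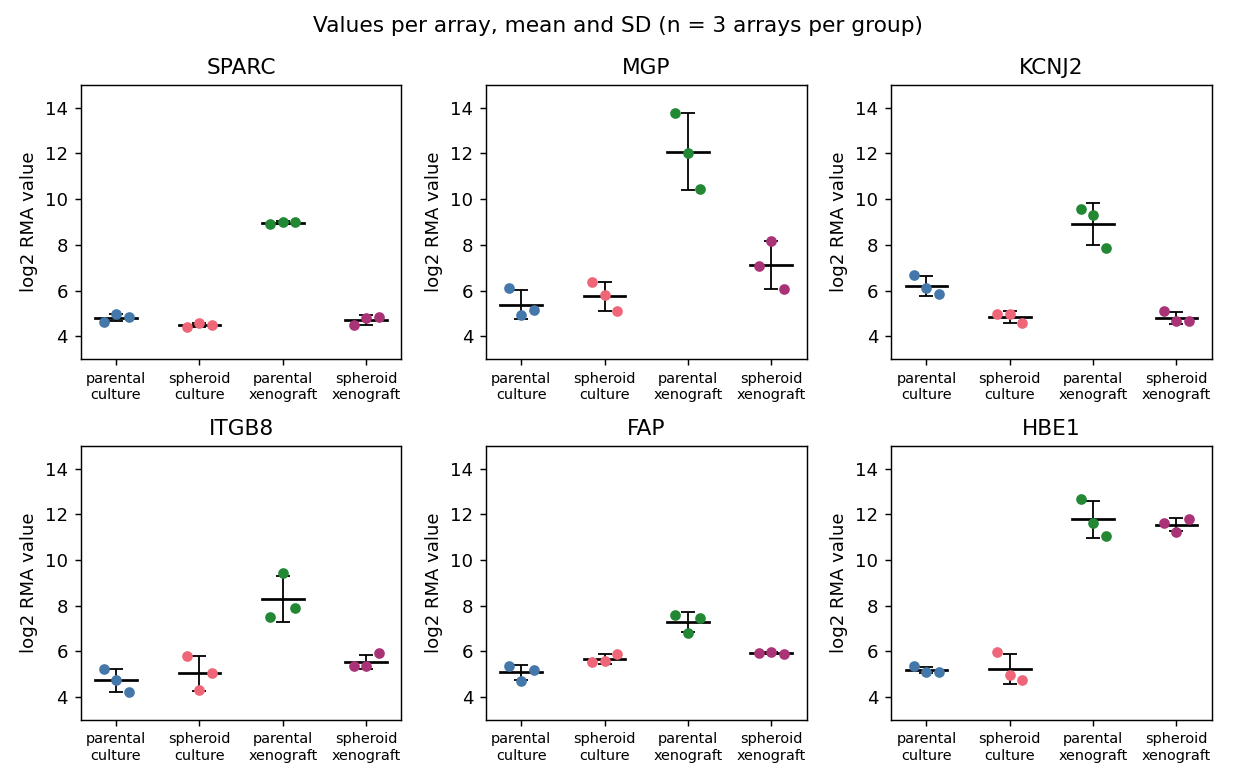
Each panel plots the log2 values of 1 gene on the 12 arrays by group, with the mean as a line and the SD as bars (n = 3 arrays per group). SPARC, MGP, KCNJ2, ITGB8 and FAP have their highest group mean in parental xenografts, and HBE1 has means of 11.77 and 11.54 in parental and spheroid xenografts against 5.18 and 5.21 in culture.

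By camera at the preset correlation, the lists of hypoxia, mesenchymal and adhesion genes were higher in parental cells grown as tumours than in culture, and those of ATF4 targets and cell cycle genes were lower. With an estimated correlation the mesenchymal list and that of integrins and laminins passed, and the others of these did not. Of 23 hypoxia genes 12 rose and 0 fell (18 rose adjusted over the list alone), with a median of 1.37. The list had camera adjusted p = 4.49e-16, and adjusted p = 0.0579 with an estimated correlation. They included ANKRD37 (3.60, SE 0.45), PDK1, a kinase that restrains pyruvate oxidation (2.33, SE 0.38), and ADM (1.82, SE 0.41). The glycolytic enzymes ALDOA (1.17, SE 0.28), LDHA (1.03, SE 0.22) and TPI1 (0.74, SE 0.16) were the 3 of 16 that rose (6 adjusted over the list alone; median 0.46; adjusted p = 7.26e-07, and adjusted p = 0.208 with an estimated correlation). Of 21 ATF4 targets 4 fell (12 adjusted over the list alone), including CHAC1 (-2.35, SE 0.25), the cystine transporter SLC7A11 (-1.91, SE 0.45) and STC2 (-1.68, SE 0.17), with a median of -0.94. Camera gave the list adjusted p = 1.32e-11, and adjusted p = 0.235 with an estimated correlation.

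Of 25 G2 and M phase genes 1 fell in parental xenografts (3 adjusted over the list alone), the centromeric histone CENPA (-0.76, SE 0.16), with a median of -0.45. The test of this list gave adjusted p = 6.36e-07, and adjusted p = 0.404 with an estimated correlation. Of 23 S phase genes 1 fell (3 adjusted over the list alone), cyclin E1, CCNE1 (-0.90, SE 0.21), with a median of -0.37. The list had adjusted p = 4.09e-05, and adjusted p = 0.450 with an estimated correlation. Of 22 stem cell markers 1 fell (1 adjusted over the list alone), ABCB1 (-1.14, SE 0.26), while CD44 differed by -0.045 (SE 0.33, adjusted p = 0.992).

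Of 16 mesenchymal genes 5 rose and 1 fell in parental xenografts (8 and 1 adjusted over the list alone; median 0.69; adjusted p = 4.48e-07, and adjusted p = 0.0303 with an estimated correlation), among them SPARC (4.15, SE 0.14), fibronectin, FN1 (4.02, SE 0.77), and the calcium-binding protein S100A4 (3.09, SE 0.41). Of 18 integrins and laminins 5 rose (8 adjusted over the list alone; median 0.36; adjusted p = 4.09e-05, and adjusted p = 0.0303 with an estimated correlation), including ITGB8 (3.55, SE 0.48), ITGAV (1.77, SE 0.29) and ITGA1 (1.40, SE 0.22). Of 18 actin cytoskeleton and SRF targets 4 rose (8 adjusted over the list alone; median 0.34; adjusted p = 2.17e-05, and adjusted p = 0.0815 with an estimated correlation), including the myosin light chain MYL9 (2.21, SE 0.26), FHL2 (1.06, SE 0.15) and ZYX (0.95, SE 0.19). ADAMTS1 (1.65, SE 0.28) and MMP16 (1.37, SE 0.20) were the 2 of 18 matrix metalloproteinases and related genes that rose (3 adjusted over the list alone; median 0.69; adjusted p = 5.42e-04, and adjusted p = 0.0647 with an estimated correlation).

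Fibroblast markers moved with these lists: 5 of 17 rose (9 adjusted over the list alone; median 0.44; adjusted p = 1.47e-05, and adjusted p = 0.208 with an estimated correlation), including the collagens COL6A1 (2.26, SE 0.51) and COL3A1 (2.06, SE 0.37) and the protease FAP (2.20, SE 0.22). Without probe sets ending in _x_at or _s_at COL3A1 differed by -0.015 (adjusted p = 0.997; range over its alternatives 3.18e-04 to 0.997), and the actin list did not pass (adjusted p = 0.231; range 7.44e-06 to 0.231). Among genes above the median level the fibroblast list did not pass (adjusted p = 0.0807; range 3.58e-08 to 0.0807). Markers of endothelial cells (adjusted p = 0.512), myeloid cells (0.436), lymphocytes (0.871), skeletal muscle (0.263), adipocytes (0.470), erythroid cells (0.841) and keratinocytes (0.332) did not pass. The highest member of each list differed by 0.62 (SE 0.16, adjusted p = 0.0627) for endothelial ENG, by 0.93 for myeloid LAPTM5, 0.37 for lymphocyte CORO1A, 0.058 for muscle MYH2, 0.35 for adipocyte FABP4, 0.86 for erythroid HBB and 0.074 for keratinocyte IVL, and 0 of these 7 were called.

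MGP rose from 5.38 ± 0.64 in parental culture to 12.08 ± 1.67 in parental xenografts (SD, n = 3 arrays per group; 6.70, SE 0.74). HBE1, which encodes an embryonic globin, rose by 6.59 (SE 0.38, limma adjusted p = 8.22e-06) on the probe set used, while its other probe set differed by 0.076 (SE 0.18). The matrix protein EDIL3 rose by 4.34 (SE 0.73) and the secretory granule protein SCG2 by 4.32 (SE 0.72). TUBB2B (-3.41, SE 0.42), the neuritin gene NRN1 (-3.26, SE 0.26), RRAGD, a GTPase of the mTORC1 pathway (-3.06, SE 0.54), the fatty acid elongase ELOVL7 (-2.97, SE 0.39) and the guanine deaminase GDA (-2.90, SE 0.21) fell. LSR, a protein of tricellular junctions (-2.76), the desmoglein DSG2 (-2.74) and BEX2 (-2.65) fell too. When probe sets ending in _x_at or _s_at were left out, the difference on other probe sets was 0.72 for MGP (adjusted p = 0.570), 0.20 for FN1 (adjusted p = 0.810), -0.27 for GDA (adjusted p = 0.629), 0.25 for TPI1 (adjusted p = 0.642), 1.09 for COL6A1 (adjusted p = 0.105) and 0.20 for MYL9 (adjusted p = 0.881), and none was called. With the mean of all probe sets SLC7A11 (0.0735), COL6A1 (0.0752) and CCNE1 (0.0643) were not called, and over all alternatives the adjusted p of these genes ran from 3.52e-06 to 0.881.

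By limma 687 genes differed between parental xenografts and parental culture, 395 higher and 292 lower in xenografts, 235 and 182 of them at 2-fold or more. After quantile normalisation again 1178 (520 higher and 658 lower) passed, after cyclic loess 1091 (478 higher and 613 lower), with only the 6 parental arrays 69, and without probe sets ending in _x_at or _s_at 441. The count was 247 without parental xenograft replicate 2, 266 without parental culture replicate 3 and 390 without parental xenograft replicate 1. It was 409 without parental xenograft replicate 3, 450 without spheroid xenograft replicate 2 and 1591 without parental culture replicate 2. Of the 38 genes named as called 25 stayed called whichever array was left out. The other 13, FN1, BEX2, ADM, SLC7A11, CENPA, ALDOA, LDHA, TPI1, COL6A1, COL3A1, ZYX, CCNE1 and ABCB1, were lost in 1 or more of these fits (adjusted p up to 0.148), 12 of them without parental xenograft replicate 2. Of the 25, with only the parental arrays in the fit PDK1 (adjusted p = 0.0699), S100A4 (0.0511), FHL2 (0.0738), ITGAV (0.102), ITGA1 (0.0738), ADAMTS1 (0.103) and MMP16 (0.0511) were not called. Without the widest array of each group DSG2 (adjusted p = 0.0501) was not called, nor were ITGAV (adjusted p = 0.123) and ADAMTS1 (0.0568) without the narrowest. Over all alternatives the adjusted p of these 8 ran from 9.14e-05 to 0.123. By camera 19 lists passed, 16 higher and 3 lower, and 2 with an estimated correlation.

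Spheroid cells grown as tumours differed from spheroid culture in 4 genes by limma, all higher. The spread was shared with variable parental culture, so 4 and the 687 of parental cells do not compare. HBE1 rose from 5.21 ± 0.66 to 11.54 ± 0.30 (SD, n = 3 arrays per group; 6.33, SE 0.38, limma adjusted p = 2.61e-05) on the same probe set, while the other differed by -0.18 (SE 0.18). TM4SF18, a membrane protein, rose by 2.96 (SE 0.33), SPAG1, which acts in the assembly of ciliary dynein, by 2.79 (SE 0.34) and LINC02591 by 1.11 (SE 0.13), the last with that sign on 1 of 2 probe sets. At an unadjusted p under 0.05 there were 1461 genes. For 3698 genes (18.7%) the groups did not overlap (13.6% in parental cells, 10% by chance). With the mean of all probe sets LINC02591 differed by 0.51 (adjusted p = 0.132; range 4.09e-04 to 0.159), and after median centring SPAG1 (0.0546) was not called (range 1.07e-04 to 0.179).

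Targets of YAP and TEAD, the interferon response and actin cytoskeleton and SRF targets were the lists higher in spheroid xenografts than in spheroid culture, with 0 members called over all genes in each. Of 22 YAP and TEAD targets 4 rose adjusted over the list alone (median 0.33; adjusted p = 3.23e-04, and adjusted p = 0.350 with an estimated correlation). Of 24 interferon response genes 8 rose adjusted over the list alone (median 0.065, mean 0.31; adjusted p = 3.23e-04, and adjusted p = 0.440 with an estimated correlation). Of 18 actin and SRF targets 2 rose and 1 fell adjusted over the list alone (median 0.28; adjusted p = 0.00785, and adjusted p = 0.440 with an estimated correlation). The phosphatase PTPN14 differed by 1.14 (SE 0.21, adjusted p = 0.0939), the antiviral enzyme OAS3 by 0.89 (SE 0.14, adjusted p = 0.0595) and MYL9 by 1.14 (SE 0.26, adjusted p = 0.145). Fibroblast markers had a median of -0.0091 and a mean of 0.25, opposite in sign (adjusted p = 0.198), with COL6A1 at 1.57 (SE 0.51, adjusted p = 0.408) and COL6A2 at 1.54 (SE 0.43, adjusted p = 0.279). The other 7 lists of cell type markers did not pass either (adjusted p from 0.198 to 0.829). CD44 differed by 0.52 (SE 0.33, adjusted p = 0.824).

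With the replicate number as a block 8 genes and 6 lists passed for spheroid xenografts against spheroid culture. The added lists were TGF-beta targets (adjusted p = 0.0287, higher), cholesterol synthesis (0.0314, lower) and the retinoid response (0.0314, lower). With an estimated correlation in that fit they had adjusted p = 0.395, 0.913 and 0.821. With the block and only the 6 spheroid arrays, a fit chosen after seeing the data, 591 (416 higher and 175 lower) genes did, and 5 lists. Called higher in it were PTPN14 (adjusted p = 0.0134), OAS3 (0.0185), MYL9 (0.0292), COL6A1 (0.00949) and COL6A2 (0.0262), and the added lists were TGF-beta targets (0.0296, higher) and matrix metalloproteinases (0.0350, lower), with adjusted p = 0.943 for each with an estimated correlation. After quantile normalisation again 40 (22 higher and 18 lower) genes passed, after cyclic loess 19 (11 higher and 8 lower), and with only the 6 spheroid arrays and no block 117. The count was 1 without spheroid culture replicate 2, 2 without spheroid xenograft replicate 2, 2 without spheroid xenograft replicate 3, 7 without spheroid xenograft replicate 1 and 7 without parental xenograft replicate 1. It was 7 without parental xenograft replicate 3, 8 without spheroid culture replicate 3, 11 without parental culture replicate 1, 20 without spheroid culture replicate 1 and 57 without parental culture replicate 2. HBE1 stayed called whichever array was left out, and TM4SF18, SPAG1 and LINC02591 were lost without spheroid culture replicate 2 (adjusted p up to 0.149 over the 12 fits). By camera 3 lists passed (0 with an estimated correlation, 4 at an unadjusted p under 0.05), and 7 without spheroid culture replicate 1. The actin list did not pass without probe sets ending in _x_at or _s_at (adjusted p = 0.744) or with array weights (0.0814; range 0.00209 to 0.744).

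The spheroid to parental difference itself differed between xenografts and culture for 27 genes by limma, 13 with a positive and 14 with a negative difference of differences. SPARC had -3.93, SE 0.20 (adjusted p = 4.37e-06), with means of 4.81 ± 0.16 in parental culture, 4.49 ± 0.081 in spheroid culture, 8.96 ± 0.060 in parental xenografts and 4.71 ± 0.20 in spheroid xenografts (SD, n = 3 arrays per group, limma). The glucose transporter SLC2A3 had -3.12, SE 0.50, CTCFL -2.99, SE 0.49, PRRX1 -2.97, SE 0.40 and the calcium-binding protein S100A16 -2.62, SE 0.26. On the positive side stood NRN1 (3.10, SE 0.36), LSR (2.53, SE 0.40), GDA (2.47, SE 0.29) and CHAC1 (2.33, SE 0.35). Without probe sets ending in _x_at or _s_at other probe sets gave 0.13 for GDA (adjusted p = 1.00), 1.04 for SMG9 (adjusted p = 0.0571) and -1.62 for SPARC (adjusted p = 0.212), and SALL3 (0.0550) and CTCFL (0.0552) were not called at an unaltered difference. With the mean of all probe sets SALL3 (0.0610), SMG9 (0.0651), SLC2A3 (0.0914) and PRRX1 (0.0753) were not called, and over all alternatives the adjusted p of these genes ran from 1.54e-07 to 1.00.

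After quantile normalisation again 133 genes passed for the interaction (79 positive and 54 negative), after median centring 8 (3 and 5), after cyclic loess 94, and with the replicate block 12. The block ended the calls of SMG9, PRRX1 and FAP (adjusted p = 0.0521 each), CHAC1 (0.0546), SLC2A3 (0.0554), PAF1 (0.0574), STARD4 and CTSA (0.0681 each) and CTCFL (0.0817), and over all their alternatives the adjusted p of these genes ran from 2.86e-04 to 0.252. SPARC and S100A16 were the 2 of 17 named genes that stayed called whichever array was left out, and the other 15 were lost without spheroid culture replicate 3 (adjusted p up to 0.158 over the 12 fits). Of those 2, S100A16 (adjusted p = 0.106) was not called without the narrowest array of each group (range 1.63e-04 to 0.106). The count was 2 without spheroid culture replicate 3, 2 without spheroid xenograft replicate 1, 2 without spheroid xenograft replicate 2, 3 without spheroid culture replicate 2 and 6 without parental xenograft replicate 2. It was 7 without spheroid xenograft replicate 3, 16 without parental xenograft replicate 1, 97 without parental culture replicate 1 and 186 without parental culture replicate 2. By camera 16 lists passed for the interaction, 5 with a positive and 11 with a negative direction, and 3 with an estimated correlation.

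PLD5, ALDOC and TNNI3 were called higher in spheroid cells both in culture and in xenografts, but with the replicate block PLD5 (adjusted p = 0.0530; range 3.94e-04 to 0.187) and ALDOC (0.0573; 7.99e-04 to 0.241) were not called between the xenografts. These 3 genes and 8 called lower in both compare with 0.0885 and 0.568 for independent lists. TNNI3 was not called between the xenografts without any 1 of 8 of the 12 arrays, spheroid xenograft replicate 2 included (adjusted p up to 0.187), after median centring, without the widest array of each group or without the narrowest (range over its alternatives 0.00153 to 0.335). The count of 11 over both directions became 18 without parental culture replicate 2, 2 without parental culture replicate 3, 48 without spheroid culture replicate 1, 1 without spheroid culture replicate 2 and 1 without spheroid culture replicate 3. It became 4 without parental xenograft replicate 1, 1 without parental xenograft replicate 2, 3 without spheroid xenograft replicate 1, 0 without spheroid xenograft replicate 2 and 6 without spheroid xenograft replicate 3. After median centring there were 3, with the replicate block 7 and without the narrowest array of each group 3. Of the 487 genes called in culture 365 (74.9%) had the same sign between the xenografts, against 59.3% of all genes. Over all genes, which are not independent replicates, these differences correlated with r = 0.371 (exact permutation p = 0.230, two-sided; rho 0.257, p = 0.360). The xenograft minus culture differences of parental and spheroid cells correlated with r = 0.350 (exact permutation p = 0.160; rho 0.296, p = 0.260), and adjusted over both tests the Pearson p was 0.230 for each. Of the 687 genes called in parental cells 535 (77.9%) had the same sign in spheroid cells, against 60.7% of all genes, and 2 were called in both (independent lists would share 0.0799). That count became 7 without parental culture replicate 1, 24 without parental culture replicate 2, 9 without spheroid culture replicate 1, 1 without spheroid culture replicate 2, 1 without spheroid xenograft replicate 2 and 1 without spheroid xenograft replicate 3.

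Spheroid culture and parental xenografts differed from parental culture in many of the same genes: 82 were called higher in both and 160 lower in both, where independent lists would share 3.50 and 4.61. The count of 242 over both directions became 388 without parental culture replicate 1, 475 without parental culture replicate 2, 115 without parental culture replicate 3 and 62 without spheroid culture replicate 2. It became 104 without spheroid culture replicate 3, 113 without parental xenograft replicate 2 and 158 without spheroid xenograft replicate 2. In opposite directions 1 was called lower in spheroid culture and higher in parental xenografts, and 0 the other way round. ADM, ANKRD37 and CTCFL were in the first set and TUBB2B, NRN1, GDA and CHAC1 in the second. Both comparisons use the parental culture arrays, which may add part of the excess. Their differences correlated over genes with r = 0.563 (rho 0.501) and a covariance of 0.104. Simulated unchanged groups had a median r of 0.530 and a mean covariance of 0.0324, and in 45 of 1000 sets the covariance was as large. That count is no test, as the simulation may understate what the shared arrays add. With different parental culture arrays behind each difference the covariance averaged 0.0454.

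**Figure D5:**
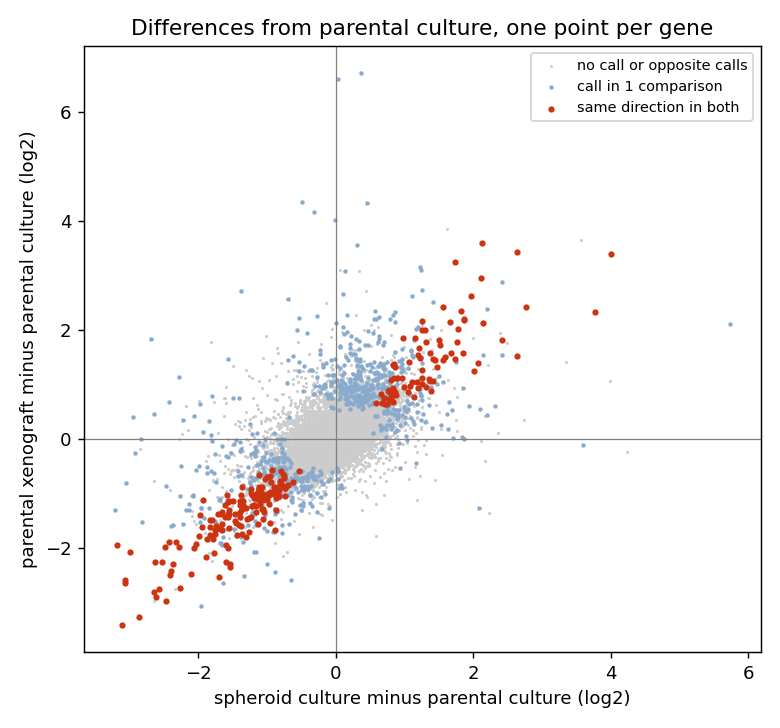
Each point is 1 of 19775 genes, with spheroid culture minus parental culture on the x axis and parental xenograft minus parental culture on the y axis, both in log2 units. The 242 genes called in the same direction in both lie in the upper right (82) and the lower left (160).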

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

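The tests of array spread and of the hypoxia list, and all tests of the genes lower in spheroid xenografts, were chosen after the results were seen, as were the fits without the widest or the narrowest array of each group, and the other tests were set before. The values below drew attention because the spheroid to parental difference in xenografts differed from that in culture by the test of that difference itself.

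The interaction was called for 27 genes by limma, of which the rule names 17. Positive values were 3.10 for NRN1, 2.53 for LSR, 2.47 for GDA, 2.33 for CHAC1, 2.21 for SALL3, 1.86 for MYO5C, 1.84 for PAF1 and 1.77 for SMG9. Negative values were -3.93 for SPARC, -3.12 for SLC2A3, -2.99 for CTCFL, -2.97 for PRRX1 and -2.62 for S100A16. They were -1.99 for the lipid droplet gene HILPDA, -1.94 for FAP, -1.77 for STARD4 and -1.52 for the lysosomal protease gene CTSA. In 100 regroupings of the 12 arrays, the real one included, 3 called as many genes, which excludes, at the 0.05 level, a random grouping that disregards the replicate numbers. Those closest below the real count called 26 and 25. With the replicate block 12 genes passed, and 9 of the genes named here did not (SMG9, PRRX1, FAP, CHAC1, SLC2A3, PAF1, STARD4, CTSA and CTCFL; adjusted p from 0.0521 to 0.0817; range over their alternatives 2.86e-04 to 0.252). Without probe sets ending in _x_at or _s_at other probe sets gave 0.13 for GDA (adjusted p = 1.00), 1.04 for SMG9 (adjusted p = 0.0571) and -1.62 for SPARC (adjusted p = 0.212), and SALL3 (0.0550) and CTCFL (0.0552) were not called at an unaltered difference. Over all alternatives their adjusted p ran from 1.54e-07 to 1.00. The highest other count was 535, from exchanging the parental and spheroid labels of all xenografts. That regrouping adds the spheroid to parental differences in culture and xenografts. The count of 27 was 2 without spheroid culture replicate 3, 2 without spheroid xenograft replicate 1, 2 without spheroid xenograft replicate 2, 3 without spheroid culture replicate 2 and 6 without parental xenograft replicate 2. It was 7 without spheroid xenograft replicate 3, 16 without parental xenograft replicate 1, 97 without parental culture replicate 1 and 186 without parental culture replicate 2.

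By camera 16 lists differed in the same way (adjusted p from 5.60e-17 to 0.0317). Of the 100 regroupings 3 called as many lists (highest other 18), with the same limit. Median differences of differences were -1.43 for the hypoxia response, -0.62 for mesenchymal genes and -0.83 for matrix metalloproteinases, with adjusted p = 0.0497, 0.0491 and 0.0491 with an estimated correlation. ATF4 targets had 1.06, cholesterol synthesis -0.36, glycolysis -0.41, endoplasmic reticulum chaperones -0.67, YAP and TEAD targets 0.17, neuroendocrine genes -0.19 and fibroblast markers -0.26, with adjusted p = 0.400 for each with an estimated correlation. Integrins and laminins had -0.35 (adjusted p = 0.0720 with an estimated correlation). The lysosome list had -0.38 and interferon response genes 0.16, with adjusted p = 0.572 for each with an estimated correlation. S phase genes had 0.23, G2 and M phase genes 0.26 and heat shock proteins -0.39, with adjusted p = 0.583, 0.601 and 0.619 with an estimated correlation. Adjusted over the list alone 16 of 23 hypoxia genes, 4 of 16 mesenchymal genes and 5 of 18 matrix metalloproteinases and related genes had a called negative value.

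The lists were refitted under 24 alternatives at the preset correlation, and those of hypoxia, glycolysis, ATF4 targets, cholesterol synthesis, endoplasmic reticulum chaperones, mesenchymal genes and matrix metalloproteinases passed under each. S phase genes passed under 23 of 24 (adjusted p 3.55e-06 to 0.0746), and not without spheroid culture replicate 1 (0.0746). Lysosome genes passed under 23 of 24 (adjusted p 1.57e-06 to 0.0556), and not without parental xenograft replicate 3 (0.0556). G2 and M phase genes passed under 23 of 24 (adjusted p 8.84e-10 to 0.462), and not without the widest array of each group (0.462). Integrins and laminins passed under 23 of 24 (adjusted p 7.37e-04 to 0.0690), and not among genes above the median level (0.0690). YAP and TEAD targets passed under 21 of 24 (adjusted p 0.00250 to 0.164), and of the single arrays the call was lost without parental xenograft replicate 1 (0.0882). Fibroblast markers passed under 20 of 24 (adjusted p 2.69e-05 to 0.572), and of the single arrays the call was lost without parental culture replicate 2 (0.0905). Neuroendocrine genes passed under 17 of 24 (adjusted p 0.00577 to 0.251), and of the single arrays the call was lost without parental culture replicate 2 (0.0828), without spheroid culture replicate 1 (0.0900) or without parental xenograft replicate 2 (0.0671). Interferon response genes passed under 15 of 24 (adjusted p 0.00322 to 0.309), and of the single arrays the call was lost without parental culture replicate 1 (0.171), without spheroid culture replicate 3 (0.154), without parental xenograft replicate 1 (0.185) or without spheroid xenograft replicate 1 (0.256). Heat shock proteins passed under 11 of 24 (adjusted p 0.00527 to 0.918), and of the single arrays the call was lost without parental culture replicate 1 (0.358), without spheroid culture replicate 3 (0.376), without parental xenograft replicate 1 (0.101), without parental xenograft replicate 3 (0.0519) or without spheroid xenograft replicate 2 (0.0676). The direction of the heat shock list turned without probe sets ending in _x_at or _s_at (median 0.0062).

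Of the genes that differed between spheroid culture and parental culture, 242 differed in the same direction between parental xenografts and parental culture, among them ADM, ANKRD37 and CHAC1 (388 without parental culture replicate 1, 475 without parental culture replicate 2, 115 without parental culture replicate 3, 62 without spheroid culture replicate 2, 104 without spheroid culture replicate 3, 113 without parental xenograft replicate 2 and 158 without spheroid xenograft replicate 2). Array spread as a covariate kept 100% of them called in both, but kept every other call too, so it cannot decide. Quantile normalisation again kept 92.1%, median centring 69.8%, leaving out each group's widest array 44.6% and its narrowest 39.3%. The 81 ways of leaving out 1 array of each group kept 0% to 82.2% (median 15.3%), so array spread stays open. With different parental culture arrays behind each difference the mean covariance over genes was 43.7% of that with all arrays (-0.0189 to 0.0918 over the splits, against 0.104), so how much the shared arrays could add stays open. A hypoxia response common to spheroids and tumours is a candidate explanation: the hypoxia list had medians of 0.84 and 1.37 in these differences, but its lowest median over the splits of the parental culture arrays was 0.496, short of the 0.5 set for it. Oxygen was not measured, and a response to the medium or to dense growth was not tested.

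The 36 genes called lower in spheroid than in parental xenografts, such as SPARC, MGP and KCNJ2, could reflect less RNA of host stroma in the spheroid tumours. Among 36 genes chosen as lowest without 1 spheroid xenograft array, that array minus parental culture had medians of -1.52 to -0.53. All genes had -0.061 to 0.090, each culture array left out in turn. For the set this argues against host stroma alone only if host RNA displaces no tumour RNA in the 2 µg labelled, which was not tested. By 95% intervals on all arrays, 24 of the 36 called genes lay below parental culture and 12, SPARC and MGP among them, did not. For those 12 the argument does not hold. Host stroma together with differences already present in culture stays open, with medians of -0.43 to 0.10 against spheroid culture: fibroblast markers passed as lower by camera (adjusted p = 2.19e-05, and adjusted p = 0.293 with an estimated correlation), while endothelial (median 0.089) and myeloid markers (median -0.028) did not pass. A difference carried over from culture stays open for the set: among genes chosen likewise without 1 array of each kind of xenograft, the difference of these 2 arrays minus that in culture had medians of -1.87 to -0.32, not all past the bound set. For 4 of the 36 genes, SPARC, S100A16, PRRX1 and FAP, the interaction was called and negative by limma. These 4 were singled out by that call, so it is no separate test of a carried-over difference, and each call ended under an alternative given before. A difference between tumours of the 2 kinds of cell, which the design names, was not tested apart from these explanations.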

How the results depend on the processing

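The fits with array spread as a covariate, without the widest or narrowest array of each group, and with the block and only the groups compared were chosen after the data were seen. Over the alternatives 173 named genes and comparisons gave 4299 results. Of these 3642 kept their direction and side of the threshold, 584 no longer passed, 72 newly passed and 1 reversed: COL3A1 in parental cells at -0.015 without probe sets ending in _x_at or _s_at. Of 25, 21, 38, 4 and 17 named genes called in culture, xenografts, parental cells, spheroid cells and the interaction, median centring ended 4, 9, 6, 1 and 10 calls, cyclic loess 0, 8, 2, 0 and 1, the mean of all probe sets 3, 5, 3, 1 and 4 and leaving out probe sets ending in _x_at or _s_at 5, 8, 7, 0 and 5, in that order. With only the groups compared, which for the interaction are all groups, 21, 1, 19 and 0 ended, without the widest array of each group 12, 13, 10, 2 and 8, and without the narrowest 3, 19, 10, 2 and 16. The values carry no background measure, so dim genes were limited only by the fit on genes above the median level. In the values that follow, culture and xenografts stand for spheroid minus parental there, and parental cells and spheroid cells for xenograft minus culture. These counts moved by over 1.5 times, and the cause was not tested.

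Camera with an estimated correlation called lists 0, 2, 2, 0 and 3. Fry called lists 0, 3, 9, 0 and 4. At an adjusted p under 0.01 there were genes 110, 5, 180, 1 and 2. At 2-fold or more there were genes 417 (parental cells). Quantile normalisation again gave genes 1096 (culture), 1178 (parental cells), 40 (spheroid cells), 133 (the interaction) and lists 10 (culture), 5 (spheroid cells). Median centring gave genes 20 (xenografts), 8 (the interaction) and lists 8 (culture), 5 (spheroid cells). Cyclic loess gave genes 971, 28, 1091, 19 and 94, and lists 9 (culture), 8 (spheroid cells). Quantile normalisation within culture and within xenografts gave genes 1067 (culture) and lists 10 (culture). The mean of all probe sets of a gene gave genes 7 (spheroid cells). Leaving out probe sets ending in _x_at or _s_at gave genes 23 (xenografts), 441 (parental cells). Genes above the median level gave genes 21 (spheroid cells) and lists 11 (parental cells), 6 (spheroid cells). Trend and robust eBayes gave genes 70 (xenografts), 12 (spheroid cells). Array weights gave genes 2095, 1206, 2343, 915 and 896, and lists 8 (culture). Only the groups compared in the fit gave genes 15 (culture), 161 (xenografts), 69 (parental cells) but 117 (spheroid cells) and lists 6 (spheroid cells). All probe sets tested singly gave genes 1276 (parental cells), 138 (spheroid cells). The replicate block gave genes 8 (spheroid cells), 12 (the interaction) and lists 10 (culture), 6 (spheroid cells). The block with only the groups compared gave genes 491 (xenografts), 591 (spheroid cells) and lists 5 (spheroid cells). Array spread as a covariate gave genes 1750, 290, 1901, 204 and 355, and lists 9 (culture), 10 (spheroid cells). Without the widest array of each group there were genes 79 (xenografts) and lists 8 (culture). Without the narrowest array of each group there were genes 5 (xenografts), 265 (parental cells), 10 (spheroid cells), 2 (the interaction) and lists 11 (spheroid cells). At an unadjusted p under 0.05 camera with an estimated correlation called 1 list in culture and 4 in spheroid cells, and fry 9 and 5. Spearman's rho was 0.501 for the differences that share parental culture. Beside the calls given with the results, the replicate block changed no other call, for xenografts and spheroid cells, of a gene named by the rule or of a list. In groups that share only a number it ended the calls of SH3BGRL in culture (0.0635; range 0.00367 to 0.282) and CCNE1 in parental cells (0.0607; range 0.00833 to 0.155), and of CAP2 and UGT8, outside the rule there, in culture. Over all groups 11 of 18 same-number pairs had r over 0.1, and 2 of 12 arrays were closest to their own number.

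Leaving out each array in turn gave genes 77 to 853, 4 to 140, 247 to 1591, 1 to 57 and 2 to 186. Lists ran 4 to 12, 8 to 15, 16 to 21, 3 to 7 and 14 to 18. The correlations over genes ran from 0.292 to 0.454 for spheroid minus parental, 0.266 to 0.412 for xenograft minus culture and 0.506 to 0.638 for the differences that share parental culture. An arm then holds 2 arrays and leans on the spread of the other groups.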

Other observations

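All tests of the HBE1 probe set, and the fits without the widest or the narrowest array of each group, were chosen after the results were seen, while the counts over other splits of the samples and the gene lists were set before.

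By camera, parental xenografts also had higher levels than parental culture on 9 lists not yet described, none of which passed with an estimated correlation. The genes named for them, except SCG2, were chosen after their values were seen. On the Notch list the ligand gene JAG1 (3.24, SE 0.40), the target HES4 (7.55 ± 0.38 to 9.06 ± 0.34, SD, n = 3 arrays per group) and the receptor gene NOTCH2 (0.91, SE 0.20) rose, and the ligand gene DLL3 (-1.07, SE 0.17) fell. That was, by limma, 3 up and 1 down of 17 (4 and 1 adjusted over the list alone; median 0.11; camera adjusted p = 0.0485, and adjusted p = 0.208 with an estimated correlation). Of 16 TGF-beta targets 2 rose (4 adjusted over the list alone), PMEPA1 (3.14, SE 0.42) and SKIL (1.47, SE 0.35), both of which restrain that pathway. The list had a median of 0.32 and adjusted p = 0.00496, and adjusted p = 0.0815 with an estimated correlation. The chemokine gene CXCL1 (2.12, SE 0.50) and the inhibitor gene NFKBIA (0.94, SE 0.18) were the 2 of 21 NF-kappaB targets that rose (2 adjusted over the list alone; median 0.22; adjusted p = 0.0297, and adjusted p = 0.235 with an estimated correlation).

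Among 18 lysosome genes 1 rose in parental xenografts, CTSA (1.31, SE 0.16), or 5 adjusted over the list alone (median 0.40; adjusted p = 7.40e-04, and adjusted p = 0.450 with an estimated correlation). The disulfide isomerase gene PDIA4 (0.94, SE 0.16) and CRELD2 (0.72, SE 0.17) were the 2 of 16 endoplasmic reticulum chaperones that rose (3 adjusted over the list alone; median 0.44; adjusted p = 0.00281, and adjusted p = 0.391 with an estimated correlation). The small heat shock protein gene HSPB1 (1.11, SE 0.19) was the 1 of 11 on its list (2 adjusted over the list alone; median 0.36; adjusted p = 0.00496, and adjusted p = 0.450 with an estimated correlation). SQLE, squalene epoxidase (0.79, SE 0.18), was the 1 of 19 for cholesterol synthesis (1 adjusted over the list alone; median 0.23; adjusted p = 0.00496, and adjusted p = 0.467 with an estimated correlation). SCG2 (4.32, SE 0.72) was the 1 of 17 neuroendocrine genes (2 adjusted over the list alone; median 0.13; adjusted p = 0.0367, and adjusted p = 0.353 with an estimated correlation). Of 18 cytosolic ribosomal proteins 0 were called by limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05; median 0.23; adjusted p = 0.0389, and adjusted p = 0.826 with an estimated correlation).

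Of these lists only that of the lysosome passed under all 25 alternatives at the preset correlation (adjusted p up to 0.0448). Endoplasmic reticulum chaperones passed under 24 of 25 (adjusted p 6.70e-04 to 0.0720), and not among genes above the median level (0.0720). TGF-beta targets passed under 23 of 25 (adjusted p 1.47e-04 to 0.130), and not among genes above the median level (0.0720) or without the widest array of each group (0.130). Cholesterol synthesis passed under 20 of 25 (adjusted p 3.24e-04 to 0.468), and of the single arrays the call was lost without parental culture replicate 1 (0.143). Neuroendocrine genes passed under 21 of 25 (adjusted p 0.00942 to 0.171), and of the single arrays the call was lost without parental culture replicate 2 (0.171) or without parental xenograft replicate 2 (0.136). Heat shock proteins passed under 18 of 25 (adjusted p 0.00150 to 0.468), and of the single arrays the call was lost without parental culture replicate 1 (0.143). NF-kappaB targets passed under 17 of 25 (adjusted p 0.0107 to 0.393), and of the single arrays the call was lost without parental culture replicate 2 (0.164) or without parental xenograft replicate 3 (0.113). The Notch list passed under 16 of 25 (adjusted p 0.00855 to 0.277), and of the single arrays the call was lost without parental culture replicate 2 (0.237), without parental culture replicate 3 (0.126), without spheroid culture replicate 2 (0.0527), without parental xenograft replicate 2 (0.0895), without parental xenograft replicate 3 (0.0514) or without spheroid xenograft replicate 2 (0.0536). Ribosomal proteins passed under 16 of 25 (adjusted p 0.00143 to 0.633), and of the single arrays the call was lost without parental culture replicate 1 (0.275) or without parental xenograft replicate 3 (0.219). The median of the ribosomal list turned to -0.075 after quantile normalisation again, -0.077 after cyclic loess, -0.097 without parental culture replicate 1 and -0.082 without the narrowest array of each group.

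In culture and in xenografts alike, 8 genes were called lower in spheroid than in parental cells, where genes outside the rule are named after their values were seen. In culture and xenografts the differences were -2.68 and -2.93 for the fibrillin FBN2, -2.42 and -2.69 for OSBPL6, -2.22 and -3.54 for CAP2 and -1.81 and -2.69 for the protocadherin PCDH7. They were -1.76 and -1.16 for SLITRK5, -1.49 and -1.88 for the protease ADAMTS3, -1.24 and -1.51 for the guanylate cyclase GUCY1B1 and -1.18 and -1.97 for UGT8. With the replicate block 4 genes were lower in both, of these 8 only PCDH7 and GUCY1B1. FBN2 (adjusted p = 0.0573), OSBPL6 (0.0573), ADAMTS3 (0.0558) and SLITRK5 (0.0614) were not called between the xenografts (range over their alternatives 7.45e-05 to 0.419). CAP2 (0.0515) and UGT8 (0.0530) were not called in culture. The number lower in both became 1 without parental culture replicate 3, 23 without spheroid culture replicate 1 and 0 without spheroid culture replicate 2 or 3. It became 4 without parental xenograft replicate 1, 1 without parental xenograft replicate 2, 1 without spheroid xenograft replicate 1 and 0 without spheroid xenograft replicate 2.

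The probe set of HBE1 was higher in both kinds of xenograft than in culture, by 6.59 and 6.33. The other HBE1 probe set differed by 0.076 and -0.18, which argues against human HBE1 transcript in the tumour cells as the source. Blood RNA of the host read through human probes is a candidate source: 0 of 18 probe sets of other globin genes were called higher by limma (4 at an unadjusted p under 0.05, largest difference 0.86). Their 95% intervals reached up to 1.52, so this stays open. Probe sequences were not used here.

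For 3 against 3 arrays the 10 splits are too few for a share under 0.05. Splits with as many genes as the real one numbered 1 in culture (real 487, highest other 1) and 1 in xenografts (46 and 0). They numbered 1 in parental cells (687 and 1) and 2 in spheroid cells (4 and 4). As many lists came from 6 splits (real 5, highest other 12), 6 (9 and 11), 1 (19 and 14) and 8 (3 and 9) in the same order. Outside parental cells, regrouped arrays thus called as many lists or more. If the replicate numbers pair the samples, 4 splits part 3 pairs, as the real one does. The highest other of these called 0 genes and 11 lists between xenografts and 0 genes and 5 lists for spheroid xenografts against culture. The 6 splits that part 1 pair reached 0 genes and 11 lists, and 4 genes and 9 lists.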
